A study of Homo sapiens with 4 samples.

How the data were processed

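ATAC-seq libraries were made from nuclei of 50000 Huh7 cells each, 1 library per group, for shControl and shARID1A cells in DMSO or 100 nM rapamycin for 6 h, per the labels. Reads were processed with BWA and MACS2 2.0 on GRCh38 (hg38), per the submitters' processing notes. The settings of the aligner and the peak caller, the treatment of the transposase offset, duplicates and mitochondrial reads, and the read depth are not given in the sources used here. Each of the 4 peak lists belongs to 1 library, so peaks were listed per library and not on pooled samples, per the labels. The columns are a peak number, chromosome, start, end, score, annotation, distance to the nearest TSS and nearest gene, per the file headers. The deposited score of each peak is the authors' own value, whose scale is not given in the sources used here. It has a minimum of 1.30 or 1.31 in every list, and was used only to rank and filter peaks within a list. Coordinates are printed as the authors deposited them.

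The peak numbers of a list follow genome order, which allowed skipped numbers to be placed between neighbouring peaks. The highest number was 52192 in shControl DMSO, 50876 in shControl rapamycin, 52366 in shARID1A DMSO and 44760 in shARID1A rapamycin, against 52192, 49783, 45700 and 44760 peaks listed. What the skipped numbers stood for is not given in the sources used here. An upper bound on the lost or gained peaks that they could account for was found by giving each skipped number to 1 such peak in its interval. Skipped numbers left over could stand for further peaks that count in the other direction, and none were added for them. A second estimate took the excess of lost peaks in intervals with skips over the rate in other intervals of similar length, and came to 3393 peaks for the loss with knockdown in DMSO, where the upper bound was 4367.

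All comparisons were computed with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures drawn with matplotlib 3.10.9. A peak was lost in a comparison if it overlapped no peak of the other list by at least 1 bp, and gained in the converse case. Comparisons were shARID1A against shControl in DMSO and in rapamycin, and rapamycin against DMSO in shControl and in shARID1A. Shares have exact (Clopper-Pearson) binomial 95% intervals. No p-value was computed, since a group held 1 library. Peaks centred within 1 kb of the nearest TSS by the authors' distance were promoter peaks and all others distal. Since distal peaks were weaker, their shares were also averaged over deciles of the score within a list, weighted by the number of promoter peaks in each. Overlapping peaks of the 4 lists were merged into regions. The odds ratio of concordance is the product of the numbers of regions that differ in the same direction in both comparisons, divided by the product of those that differ in opposite directions, with a Woolf 95% interval. The comparisons set side by side in it share no library.

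Genes were taken from a table of 19970 protein-coding genes of GRCh38.p14 without strand. Of 34326 nearest-gene names in the peak lists, 23844 matched this table. The TSS and strand of a gene were read from the authors' distances, for 13113 genes from peaks with different centres that gave the same TSS position within 2 bp, and for the rest from the gene end or the order of introns and exons, which gave a strand for 15790 genes. In 11787 genes both ways applied, and they gave the same strand in 99.3%. Another 3194 genes without a strand and without a peak within 2 kb of either end counted as without a promoter peak. The remaining 986 genes were left out, among them the list genes AXL, CEBPA, ASNS, IER3, CDKN1A and C1QA, so that 18984 genes were used. The design had set all annotated TSS for this step. In their place the gene end given by the strand was used, with the positions read from the authors' distances. These positions had to lie in the gene or within 1 kb of it, and a gene could have several. A gene had a promoter peak if a peak lay within 1 kb of any of its TSS.

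The gene lists were 14 lists of 311 genes: YAP/TEAD targets, hepatocyte genes, liver progenitor and biliary genes, mTORC1-linked metabolic genes, lysosome and autophagy genes, SWI/SNF subunits, AP-1 and immediate early genes, cell-cycle genes, genes of epithelial-mesenchymal transition and invasion, ribosomal protein genes, and markers of leukocytes, endothelium, stellate cells and fibroblasts, and neurons. For each list, peaks within 50 kb of the TSS of its members were added up, a peak near several members counting for each. The log2 ratio of the sums, with 1 added to each, was placed among those of 10000 random lists of the same size matched on the number of peaks. Gene density was not matched. These percentiles describe the libraries and are not tests. Lists, comparisons and the alternatives in window, overlap, promoter width and number of peaks were fixed before the data were examined. So was the rule for named items. In each comparison it takes the 6 top-ranked lost and the 6 top-ranked gained peaks on chromosomes 1 to 22 and X with no peak of the other list within 1 kb, and the up to 12 list genes whose promoter state differs, highest-ranked first. It also takes ARID1A, ALB, AFP, CCN1, CCN2 and ANKRD1 in every library. Some items that the rule takes are not reported here. FOXF2 with knockdown in DMSO lies beyond the 12 and was named after its values were seen. Members named as examples of the peak numbers around a list were chosen after their values were seen.

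The steps were tested on simulated data. Of 2000 peaks removed from a copy of the list of 52192 peaks 2000 were counted as lost, and of 1000 added 1000 were counted as gained. After 4000 peaks were deleted from a numbered copy, 3915 of which the reference list held, the bound gave 3916 and the excess estimate 3976. With 60000 simulated regions, detection unequal between the lists and no effect, the knockdown odds ratio was 1.14 and the rapamycin odds ratio 1.04. These came from a single run without an interval. Unequal detection alone may therefore move the knockdown odds ratio above 1, but by how much was not measured. A seeded knockdown effect gave a knockdown odds ratio of 2.10. A list with 40% of its peaks removed, among 18984 genes, came out at percentile 0, and of 20 unchanged lists 1 lay outside the central 95%. Shares of motifs in lost and gained peaks had been planned and are not analysed here, since no genome sequence was used. No column of per-sample values was left unused.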

Results

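Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in Huh7 cells, an established human liver cancer line. The cells carried a control short hairpin RNA (shControl) or one against ARID1A (shARID1A), the DNA-binding subunit of the BAF form of the SWI/SNF chromatin remodeller. Each kind of cell received DMSO or 100 nM rapamycin, an inhibitor of the kinase complex mTORC1, for 6 h. The 4 groups held 1 library each, made from 50000 cells. With no replicates, no difference could be set against a spread between cultures, and every value describes these 4 libraries. Each library was represented by a list of peaks on GRCh38, and the read depth behind the lists was unknown.

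The list of shControl cells in DMSO held 52192 peaks over 39.9 Mb, and that of shControl cells in rapamycin 49783 peaks over 40.7 Mb. The shARID1A lists were shorter, with 45700 peaks over 38.3 Mb in DMSO and 44760 peaks over 35.1 Mb in rapamycin. Peak numbers within the lists ran without a break in shControl DMSO and shARID1A rapamycin. They skipped 1093 numbers (2.15%) in shControl rapamycin and 6666 numbers (12.7%) in shARID1A DMSO, so peaks absent from those lists were not all shown to be closed. Promoter peaks, centred within 1 kb of a transcription start site (TSS), were similar in number in the lists, at 13050 and 12933 for shControl in DMSO and rapamycin and 13067 and 12823 for shARID1A. Distal peaks, all others, numbered 39142 and 36850 in shControl and 32633 and 31937 in shARID1A. The promoter share was therefore at most 26.0% in the shControl lists and 28.6% in both shARID1A lists, and introns held between 35.1% and 38.4% of the peaks of a list.

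Promoters of housekeeping genes were open in every list. All 30 ribosomal protein genes and all 29 cell-cycle genes examined had a promoter peak in all 4 libraries, as did 28 of 29 mTORC1-linked metabolic genes. Of 29 hepatocyte genes, 16 had a promoter peak in shControl DMSO and 18 in each of the other lists. Among genes of other cell types, promoter peaks were present at 4, 3, 3 and 3 of 14 leukocyte markers, 1, 0, 1 and 2 of 12 endothelial markers, 6, 6, 6 and 5 of 12 stellate cell and fibroblast markers, and 7, 5, 6 and 5 of 12 neuron markers in shControl DMSO, shControl rapamycin, shARID1A DMSO and shARID1A rapamycin. In the same order, promoter peaks were present at 20, 19, 20 and 19 of 21 YAP/TEAD target genes, 12, 11, 12 and 12 of 15 liver progenitor and biliary genes, 28, 28, 28 and 27 of 29 lysosome and autophagy genes, 24, 25, 27 and 25 of 27 SWI/SNF subunit genes, 21, 20, 21 and 20 of 22 AP-1 and immediate early genes, and 18, 17, 18 and 18 of 23 genes of epithelial-mesenchymal transition and invasion.

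ARID1A itself had a promoter peak in all 4 lists, at chromosome 1, 26695459 to 26695918 in shControl DMSO. A short hairpin RNA acts on the transcript, so this peak does not check the knockdown, and transcript and protein levels were not analysed here. Peaks were ranked within each list by the score that the authors deposited with them. The ARID1A promoter peak ranked 8234 of 52192 in shControl DMSO, 7781 of 49783 in shControl rapamycin, 10627 of 45700 in shARID1A DMSO and 11601 of 44760 in shARID1A rapamycin. The YAP/TEAD targets CCN1, CCN2 and ANKRD1 had promoter peaks in all lists. The CCN2 peak ranked 7744 in shControl DMSO and 27519 in shControl rapamycin, against 6620 and 4914 in the shARID1A lists. In percent of list length these ranks were 14.84, 55.28, 14.49 and 10.98. Unequal list length therefore does not produce the weaker rank in shControl rapamycin. From DMSO to rapamycin, CCN1 went from 17.13 to 30.53 in shControl and from 19.63 to 15.43 in shARID1A. ANKRD1 went from 9.73 to 16.43 in shControl and from 10.76 to 7.16 in shARID1A. With 1 library per group, these rank differences were not tested. ALB, encoding serum albumin, and AFP, encoding the fetal liver protein alpha-fetoprotein, had no promoter peak in any list. Both lie in neighbourhoods that held peaks: within 50 kb of the TSS, ALB had 9, 7, 6 and 5 peaks and AFP 9, 7, 7 and 4 in shControl DMSO, shControl rapamycin, shARID1A DMSO and shARID1A rapamycin.

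The comparison of shARID1A with shControl cells in DMSO asked which accessible regions differed with ARID1A knockdown alone. Peaks of shControl without an overlapping peak in shARID1A are called lost, and the converse gained. Distal peaks made up most of the lost peaks: 34.9% of shControl distal peaks were lost (95% interval 34.4 to 35.4, exact binomial; all intervals on shares cover counting error only), against 5.82% of promoter peaks (5.43 to 6.24). Distal peaks were weaker, and weighted to the score deciles of the promoter peaks their lost share was 12.2%. For gained peaks the shares matched in this way were 6.77% for distal and 6.56% for promoter peaks. In all, 14428 of 52192 peaks were lost (27.6%, 27.3 to 28.0) and 8079 of 45700 were gained (17.7%, 17.3 to 18.0). Peaks lost were weak ones for the most part, and among the stronger 50% of each list 1150 peaks (4.41%) were lost and 468 (2.05%) gained. The 6666 skipped numbers could hold at most 4367 of the lost peaks, which would leave 10061. Among the stronger 50% the same bound would leave 587 of the 1150 lost peaks. Skipped numbers that match no lost peak could stand for further gained peaks, which were not added to the 8079. Whether lost peaks would still outnumber gained ones after filling in was therefore not determined.

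The strongest regions lost with knockdown in DMSO included peaks annotated to gene promoters. They were the peak at the zinc finger gene ZNF286A (chromosome 17, 15699519 to 15699863), that at the ubiquitin-conjugating enzyme variant gene UBE2V1 (chromosome 20, 50115771 to 50116165), counted as distal above because the authors' distance to its TSS was -2770 bp, and the peak at CENPB, encoding a centromere protein (chromosome 20, 3786733 to 3787315), which lay 73 bp from the TSS of the cell-cycle phosphatase gene CDC25B. The other 3 were a region in intron 2 of C3orf52 (chromosome 3, 112097454 to 112097782), an intergenic region at 90293905 to 90294241 on chromosome 5 with CETN3 as the nearest protein-coding gene, and an intergenic region near the centromere of chromosome 10 (41879303 to 41879632). The strongest gained regions were promoter regions of SKI, encoding a repressor of TGF-beta signalling (chromosome 1, 2227436 to 2227961), NSG2 (chromosome 5, 174045350 to 174045780) and MLLT1 (chromosome 19, 6279946 to 6280322), an intergenic region 7815 bp from the TSS of ID1, an inhibitor of basic helix-loop-helix factors (chromosome 20, 31612895 to 31613301), and intergenic regions on chromosome 4 (49136787 to 49137316) and at the start of chromosome 5 (11455 to 11784). SKI, NSG2 and MLLT1 had these peaks in every list except shControl DMSO, and UBE2V1 in every list except shARID1A DMSO.

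At the gene level in DMSO, 281 of 12601 genes with a promoter peak in shControl lacked one in shARID1A (2.23%), and 485 of 12805 had one in shARID1A alone (3.79%). Among hepatocyte genes, the promoters of APOA2, an apolipoprotein of high-density lipoprotein, NR1I2, the xenobiotic receptor PXR, and AHSG, the plasma protein fetuin-A, were gained, and that of NR1H4, the bile acid receptor FXR, was lost. Among SWI/SNF subunits SMARCD3, BCL7A and ACTL6B, a subunit of the neuronal complex, gained a promoter peak. CDH1, encoding E-cadherin, gained one and TWIST1, a transcription factor of epithelial-mesenchymal transition, lost one, although shARID1A DMSO skips a number in the interval around the TWIST1 peak. Of the YAP/TEAD targets FJX1 gained a promoter peak and FOXF2 lost one, the latter in an interval where shARID1A DMSO skips a number. The neuron marker STMN2 and the T cell marker CD3D each lost one. APOA2, NR1I2 and SMARCD3 lacked a promoter peak in shControl DMSO alone, and STMN2, CD3D and FOXF2 had one there alone. The AHSG peak ranked 43510 of 45700 in shARID1A DMSO.

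Neighbourhoods of liver progenitor and biliary genes held fewer peaks with knockdown in DMSO. Counted within 50 kb of each TSS and added over the 15 genes, 73 peaks in shControl compared with 57 in shARID1A, a log2 ratio of -0.35 at percentile 0.28 among 10000 random gene lists matched on peak number. Of the 15 genes 10 had fewer peaks, 0 had more and 5 had the same number. SOX9, a biliary and progenitor transcription factor, had 6 and 3, and EPCAM, an epithelial adhesion molecule, had 7 and 5. DLK1, a fetal liver gene, had 3 and 0. YAP/TEAD target neighbourhoods held 118 and 105 peaks (log2 ratio -0.17, percentile 7.25), inside the central 95% of random lists, while within 10 kb the ratio was -0.31, at percentile 0.825, and with equal numbers of peaks it was -0.03, at percentile 6.57. MYOF had 8 and 5, NT5E 6 and 4 and CCN1 7 and 5, against 5 and 7 for CCN2 and 5 in both for ANKRD1. Among markers of other cell types, those of leukocytes held 58 and 49 (log2 ratio -0.24, percentile 6.36), and -0.15 at percentile 2.45 was found with equal numbers of peaks. Stellate cell and fibroblast markers held 37 and 32 (log2 ratio -0.20, percentile 19.5). Their ratio was -0.49 at percentile 0.585 within 10 kb but 0.14 at percentile 62.4 with equal numbers. Endothelial markers held 30 and 29 (percentile 62.6) and neuron markers 38 and 35 (percentile 29.7). Hepatocyte gene neighbourhoods held 166 and 170 (log2 ratio 0.03, percentile 78.3), and of the 29 genes 7 had fewer peaks, 13 more and 9 the same number. HNF4A had 9 and 11 and FOXA2 6 and 9, while ALB had 9 and 6. With the same number of top-ranked peaks from each list the progenitor ratio was -0.10, at percentile 3.48, and with a 10 kb window it was -0.12, at percentile 26.3. The shARID1A DMSO list skips 12.7% of its numbers, so part of these lower counts may be missing rows. In this and the other comparisons the random lists were not matched on gene density, along which the loss of distal peaks differed. A low percentile may therefore reflect where the genes of a list lie.

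**Figure D1:**
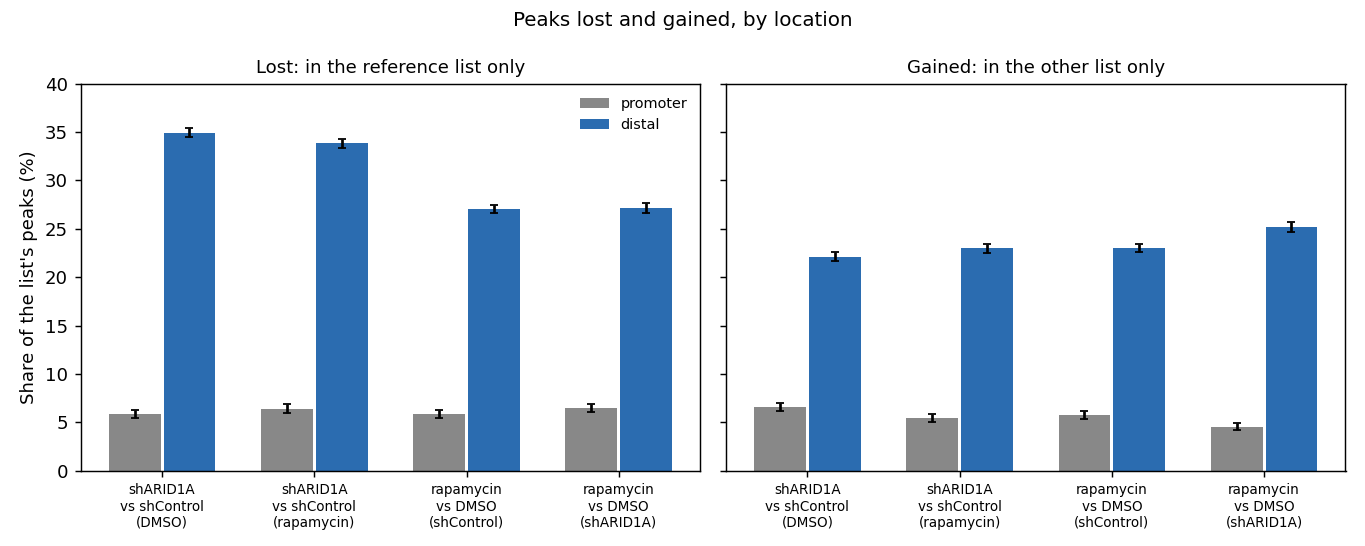
Share of peaks lost (left) and gained (right) in each of the 4 comparisons, in percent of the list that holds them, for promoter (grey) and distal (blue) peaks, with exact binomial 95% intervals for counting error as error bars and 1 library per group. Distal peaks were lost in 34.9% and 33.8% with knockdown in DMSO and rapamycin and in 27.0% and 27.1% with rapamycin in shControl and shARID1A, and promoter peaks in between 5.81% and 6.50%.

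The comparison of shARID1A with shControl cells under rapamycin asked the same question in treated cells, with another pair of libraries and with few skipped numbers. Distal peaks again made up most of the lost peaks, with 33.8% of shControl distal peaks lost (33.4 to 34.3) against 6.41% of promoter peaks, and 11.2% of distal peaks when weighted to the promoter peaks' score deciles. In all, 13299 of 49783 peaks were lost (26.7%, 26.3 to 27.1) and 8030 of 44760 gained (17.9%, 17.6 to 18.3). Among the stronger 50%, 1051 were lost (4.22%) and 530 gained (2.37%). Taking the same number of top-ranked peaks from every list gave 9443 lost and 9164 gained here, and 9053 and 9092 in DMSO. Lists of equal length give nearly equal numbers lost and gained whatever the cause. This run therefore cannot separate the larger number lost from the longer shControl lists.

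The strongest region lost under rapamycin lay in intron 3 of MBTPS1, encoding the site-1 protease that cleaves SREBP transcription factors (chromosome 16, 84096538 to 84097158). Next were the CENPB and CDC25B promoter region, also lost in DMSO, a region on chromosome 17 (25920080 to 25920385), one 23721 bp from the TSS of the immediate early gene IER5 (chromosome 1, 181111951 to 181112891), one in intron 3 of ATG7, encoding an enzyme of autophagosome formation (chromosome 3, 11302495 to 11303022), and the promoter of the non-coding gene AC131212.1 (chromosome 12, 132593765 to 132594234). The peaks at MBTPS1, IER5, ATG7 and AC131212.1 were present in shARID1A DMSO and absent only from shARID1A rapamycin. The strongest gained region was the one near ID1 that was also gained in DMSO (chromosome 20, 31612888 to 31613293). It was followed, among others, by the promoter of PDXDC1 (chromosome 16, 14974931 to 14975315), a region 12094 bp from the TSS of the calcium channel gene TRPV4 (chromosome 12, 109845210 to 109845775), exon 1 of RAB37 (chromosome 17, 74671091 to 74671655) and an intergenic region of chromosome 22 (12166462 to 12167253). The peaks of PDXDC1, TRPV4, RAB37 and chromosome 22 were present in shControl DMSO and absent only from shControl rapamycin.

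Under rapamycin, 373 of 12687 genes lost their promoter peak with knockdown (2.94%) and 324 of 12638 gained one (2.56%). With equal numbers of peaks the balance turned, with 270 genes losing and 419 gaining one. As in DMSO, NR1H4 and TWIST1 lost a promoter peak and CDH1 gained one. The NR1H4 peaks of both shControl lists overlapped. The CDH1 peaks of the shARID1A lists (chromosome 16, 68738177 to 68738696 in DMSO and 68737237 to 68737604 in rapamycin) did not overlap, nor did the TWIST1 peaks of the shControl lists (chromosome 7, 19116542 to 19116867 and 19117263 to 19117671). The TWIST1 peak ranked 46490 of 49783 in shControl rapamycin, and that of NR1H4 46238. MITF, a transcription factor of lysosome genes, and the fibroblast marker LUM, encoding the matrix proteoglycan lumican, were lost under rapamycin alone, a difference that was not tested. Among the list genes that gained a promoter peak were the matrix glycoprotein gene SPARC, the endothelial markers CLDN5 and LYVE1 and the hepatocyte gene TTR, encoding transthyretin. TTR lay in an interval where shControl rapamycin skips a number. SPARC and LYVE1 lacked a promoter peak in shControl rapamycin alone, while TTR and CLDN5 had one in shARID1A rapamycin alone.

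YAP/TEAD target neighbourhoods held fewer peaks with knockdown under rapamycin, 118 in shControl and 96 in shARID1A (log2 ratio -0.29, percentile 0.21). Of the 21 genes 13 had fewer peaks and 0 had more, and 8 had fewer both here and in DMSO. The membrane repair protein gene MYOF had 6 and 5 peaks, NT5E, encoding the ecto-enzyme CD73, 4 and 3, and GADD45A, a stress response gene, 6 and 3. The targets named in advance held even numbers, with CCN1 at 6 and 6, CCN2 at 6 and 6 and ANKRD1 at 5 and 5. The guanine exchange factor genes ARHGEF17 and DOCK5 had 14 and 10 and 7 and 4. The ratio was -0.15 at percentile 0.495 with equal numbers of peaks and -0.23 at percentile 3.98 with a 10 kb window. Progenitor and biliary genes had 66 and 53 peaks (log2 ratio -0.31, percentile 1.67), with AFP at 7 and 4, SOX9 at 4 and 3 and DLK1 at 1 and 0. That ratio was -0.08 at percentile 15.5 with equal numbers and -0.06 at percentile 41.1 with the 10 kb window. The hepatocyte list had 163 and 162 peaks (log2 ratio -0.01, percentile 81.0).

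The knockdown differences could be compared between treatments without any shared library. Peaks of the 4 lists merged into 69838 regions, of which 31585 (45.2%) were present in all lists, with 81.8% of promoter and 34.5% of distal regions among them. Of the regions that differed with knockdown in both treatments, 3648 were present only in both shControl lists and 1265 only in both shARID1A lists. That imbalance was smaller with equal numbers of peaks, at 2395 and 1773, and outside intervals with skipped numbers, at 1933 and 1087. In the opposite patterns, 1177 were present only in shControl DMSO and shARID1A rapamycin, and 1209 only in shControl rapamycin and shARID1A DMSO. The odds ratio of same against opposite direction was 3.24 (95% counting interval 2.93 to 3.59). It was 1.86 (1.32 to 2.62) at promoters and 11.5 (8.37 to 15.9) among regions with a peak in the stronger 50% of at least 1 list. Named regions of the first kind were the C3orf52 intron and the CENPB and CDC25B promoter region, and of the second the region near ID1 and that on chromosome 4.

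**Figure D2:**
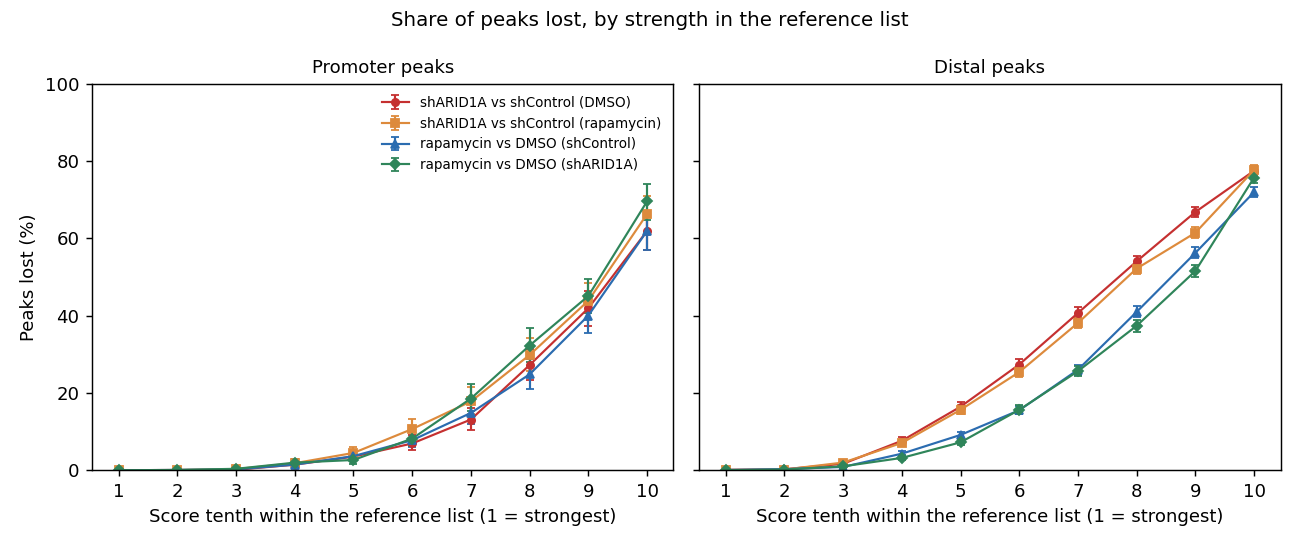
Share of promoter (left) and distal (right) peaks lost in each comparison, in percent, by decile of the authors' score within the reference list (1 is strongest), with exact binomial 95% intervals for counting error and 1 library per group. In decile 7, 40.7% and 38.1% of distal peaks were lost with knockdown in DMSO and rapamycin, and 26.0% and 25.6% with rapamycin in shControl and shARID1A.

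The comparison of rapamycin with DMSO in shControl cells asked which accessible regions differed with mTORC1 inhibition where ARID1A was not targeted. Promoters of housekeeping and metabolic genes were open in both lists, and differences lay at distal sites and at single promoters. Of 52192 peaks in DMSO 11341 were lost (21.7%, 21.4 to 22.1), and of 49783 in rapamycin 9209 were gained (18.5%, 18.2 to 18.8). Lost peaks made up 27.0% of distal peaks, 8.99% when weighted to the promoter peaks' score deciles, and 5.81% of promoter peaks, and 8469 of the gained peaks were distal and 740 at promoters. Among the stronger 50% of each list, 667 were lost and 429 gained. Taking the same number of top-ranked peaks gave 7386 lost and 7570 gained, which equal list lengths bring close together whatever the cause.

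The strongest regions lost with rapamycin in shControl were the ZNF286A promoter, a region 27912 bp from the TSS of the deubiquitinase gene USP47 (chromosome 11, 11813303 to 11813719), the region near the centromere of chromosome 10, a region 5519 bp from the TSS of ID1 (chromosome 20, 31610640 to 31610964), intron 1 of RAB11FIP5 (chromosome 2, 73089474 to 73090217) and intron 3 of the non-coding gene LINC02006 (chromosome 3, 153848652 to 153849007). The ZNF286A and chromosome 10 peaks were present in shControl DMSO alone. The strongest gained regions were the SKI promoter region (chromosome 1, 2227641 to 2227977), a region on chromosome 17 (25920080 to 25920385), the MLLT1 promoter (chromosome 19, 6279944 to 6280323), a region 50882 bp from DUX4 in a repeated stretch of chromosome 4 (190122711 to 190123074), intron 2 of the synaptic scaffold gene SHANK2 (chromosome 11, 70650267 to 70650737) and a region 22561 bp from ZNHIT3 (chromosome 17, 36463876 to 36464261). All of these gained regions except that on chromosome 17 at 25920080 were also present in both shARID1A lists.

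In shControl, 316 genes lost a promoter peak with rapamycin (2.51%) and 402 gained one (3.17%). APOA2, NR1I2 and SMARCD3, which lacked a promoter peak in shControl DMSO alone, gained one. That list is also the reference of the knockdown comparison in DMSO. STMN2, CD3D and FOXF2 had a promoter peak in it alone. The NR1I2 peak of shControl rapamycin (chromosome 3, 119780576 to 119781261) ranked 48685 of 49783. It did not overlap that of shARID1A DMSO (119781617 to 119782568). LYVE1, a hyaluronan receptor of lymphatic endothelium, the neuron markers STMN2 and ELAVL3, the T cell marker CD3D, SPARC, the YAP/TEAD target FOXF2 and MAFK, a small MAF transcription factor, were among those that lost one. No promoter among the 29 mTORC1-linked metabolic genes and the 29 lysosome and autophagy genes differed. The neighbourhoods of the mTORC1-linked genes held 131 peaks in DMSO and 127 in rapamycin (log2 ratio -0.04, percentile 45.5), and those of the lysosome and autophagy genes 133 and 131 (log2 ratio -0.02, percentile 62.9). Within the latter, the lysosomal channel gene MCOLN1 had 5 and 2 peaks, the proton pump gene ATP6V1A 4 and 1 and the autophagy gene GABARAPL1 4 and 1, while NEU1 had 9 and 12 and BECN1 4 and 7. YAP/TEAD target neighbourhoods held 118 in both. Stellate cell and fibroblast marker neighbourhoods held 37 and 29 (log2 ratio -0.34, percentile 1.89), with DES, encoding desmin, at 9 and 7 and LUM at 3 and 2. That ratio was -0.15 at percentile 13.6 with equal numbers of peaks.

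The comparison of rapamycin with DMSO in shARID1A cells asked the same of cells with ARID1A targeted. Neighbourhoods of mTORC1-linked metabolic genes held fewer peaks in rapamycin, 114 against 135 in DMSO (log2 ratio -0.24, percentile 1.19). Of the 29 genes 15 had fewer peaks, 6 more and 8 the same number. HIF1A, the hypoxia transcription factor, had 4 in DMSO and 1 in rapamycin, its target VEGFA 7 and 3, and the serine and glycine synthesis genes SHMT2 and PSAT1 8 and 5 and 3 and 1. In the cholesterol pathway, HMGCS1 had 6 and 4 and INSIG1 7 and 5, while SREBF1 had 8 and 10. The ratio was -0.23 at percentile 0.515 with equal numbers of peaks and -0.06 at percentile 45.8 with a 10 kb window. Whether this list differed between shARID1A and shControl cells was not tested.

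In shARID1A, 9707 of 45700 peaks were lost with rapamycin (21.2%, 20.9 to 21.6), and 8618 of 44760 were gained (19.3%, 18.9 to 19.6). Lost peaks made up 27.1% of distal peaks, 8.26% when weighted to the promoter peaks' score deciles, and 6.50% of promoter peaks, and gained peaks 25.2% of distal peaks, 7.05% when weighted in the same way, and 4.51% of promoter peaks. Of the gained peaks, up to 3010 could belong to numbers skipped in shARID1A DMSO, which would leave 5608. Skipped numbers that match no gained peak could stand for further lost peaks, which were not added to the 9707. The strongest lost regions lay in intron 1 of the cell polarity gene LLGL1, 169 bp from its TSS (chromosome 17, 18225322 to 18226370), at the start of chromosome 5 (11455 to 11784), at the promoter of AC131212.1 (chromosome 12, 132593859 to 132594244), in intron 1 of the growth factor gene PDGFC (chromosome 4, 156941862 to 156942260), in intron 3 of the iron reductase gene CYBRD1 (chromosome 2, 171553895 to 171554510) and 23871 bp from IER5 (chromosome 1, 181112178 to 181112965). All of these except that at the start of chromosome 5 were present in both shControl lists. Among the strongest gained regions were the promoter of UBE2V1 (chromosome 20, 50115609 to 50116138), a region on chromosome X with FAM9C as the nearest protein-coding gene (13224249 to 13224635), intron 2 of CMTM3 (chromosome 16, 66608514 to 66608834), intron 3 of SVIL (chromosome 10, 29621228 to 29621701) and an intergenic region on chromosome 10 (69696118 to 69696506). Of these, the CMTM3 region and that at 69696118 lay where shARID1A DMSO skips a number.

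At promoters in shARID1A, 423 genes lost a peak with rapamycin (3.30%) and 256 gained one (2.03%). MITF, LUM, BCL7A, ACTL6B, FJX1, ELAVL3, MAFK and AHSG lost one, and TTR and CLDN5, a tight junction gene of endothelium, gained one. MAFK and ELAVL3 were the list genes whose promoter peak was lost with rapamycin in both genotypes. BCL7A, ACTL6B, FJX1 and AHSG had a promoter peak in shARID1A DMSO alone. SWI/SNF subunit neighbourhoods held 124 peaks in DMSO and 110 in rapamycin (log2 ratio -0.17, percentile 9.20), and lysosome and autophagy neighbourhoods 136 and 128 (log2 ratio -0.09, percentile 40.2). Over 14 lists and 4 comparisons, 5 of 56 list values lay outside the central 95% of random lists, all of them below. Chance gives 2.8 above and below together. The 56 values are not independent, since the comparisons share libraries and genes.

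**Figure D3:**
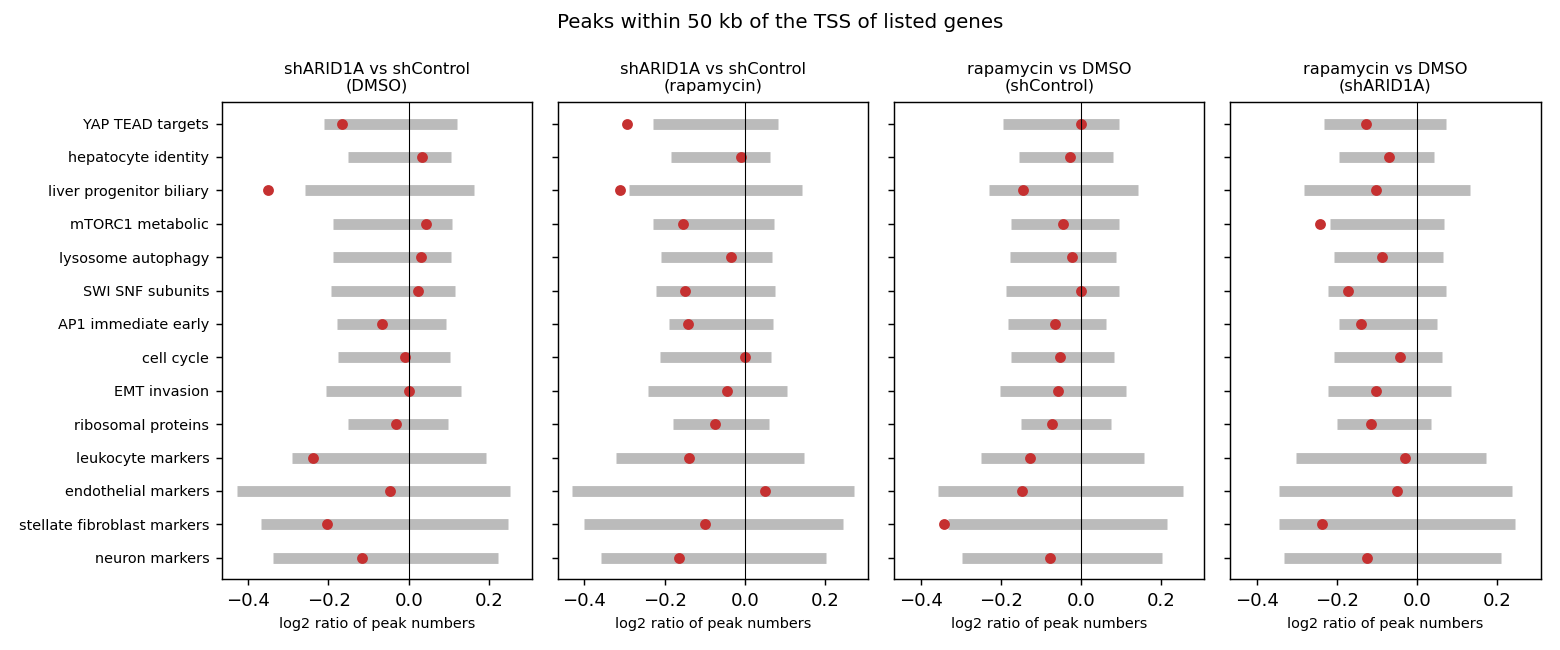
Log2 ratio of the number of peaks within 50 kb of the TSS of the members of each of 14 gene lists (points), with the central 95% of 10000 random lists matched on peak number (grey bars), in the 4 comparisons with 1 library per group. YAP/TEAD targets under rapamycin (-0.29) and progenitor and biliary genes in DMSO (-0.35) and rapamycin (-0.31) lay below the bars for knockdown, as did mTORC1-linked genes in shARID1A (-0.24) and stellate cell markers in shControl (-0.34) for rapamycin.

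Rapamycin differences went the same way in both genotypes no more often than counting error allows. Of the regions that differed with rapamycin in both, 1383 were present only in the DMSO lists and 1087 only in the rapamycin lists, with 1177 and 1209 in the opposite patterns. The odds ratio was 1.06 (0.944 to 1.18), and 0.722 (0.491 to 1.06) at promoters. The region lists also show what regions that differed with knockdown in DMSO looked like after rapamycin. Of 14271 regions lost with knockdown, 3465 (24.3%) had a peak in shARID1A rapamycin, and 5936 (41.6%) in shControl rapamycin. The lost regions can include peaks at numbers skipped in shARID1A DMSO. A peak in shARID1A rapamycin therefore does not show that a region reopened. Of 7905 regions gained with knockdown, 2671 (33.8%) had a peak in shARID1A rapamycin and 2615 (33.1%) in shControl rapamycin.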

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

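The tests of skipped peak numbers were chosen after the results they bear on had been seen, and that among stronger peaks after the data but before its own value was seen, as were those within gene-density deciles, within chromosomes and across chromosomes, while the runs with equal numbers of peaks and away from promoters were planned before the data were examined and set against an explanation after their values were seen.

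The balance of promoter peaks differed between treatments and between genotypes, a difference that was not tested. Genes gaining a promoter peak with knockdown outnumbered those losing one by 204 in DMSO, while the same difference under rapamycin was -49. The opposite balance with knockdown was not kept with equal numbers of peaks. Then 604 genes gained and 156 lost a promoter peak in DMSO, and 419 gained and 270 lost one under rapamycin. Under rapamycin only the shControl list was shortened by this, which can only lower the losses and raise the gains. The cause of the opposite balance therefore stays untested. For rapamycin against DMSO the difference was 86 in shControl and -167 in shARID1A, and equal numbers of peaks gave 410 gained and 242 lost in shControl and 264 gained and 395 lost in shARID1A. The peak on chromosome X at 13224249 to 13224635, with FAM9C as the nearest protein-coding gene, was present in shControl DMSO and shARID1A rapamycin but in neither of the other lists. It was thus lost with knockdown in DMSO and gained with it under rapamycin, again untested.

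Both shARID1A lists were shorter than the shControl list of the same treatment. In DMSO the shARID1A list held 6492 fewer peaks, but its highest peak number was above that of shControl (a difference of -174), so the skipped numbers may account for the whole shortfall there. Under rapamycin the shortfall was 5023 peaks and the highest numbers differed by 6116, which skipped numbers cannot produce. A difference in read depth or library quality stays open for both, since neither was known, beside an effect of ARID1A knockdown.

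Regions that differed with knockdown in both DMSO and rapamycin tended to differ in the same direction, with an odds ratio of 3.24. They were a minority. Of 14271 regions lost in DMSO, 3648 were also lost under rapamycin. Of 7905 regions gained in DMSO, 1265 were also gained under rapamycin and 1209 were lost there. With equal numbers of peaks these counts for gained regions were 1773 and 1129. Unequal list length, a larger promoter share of both shARID1A lists, and weak peaks near the calling threshold each predicted a ratio of about 1 once removed. The ratio was 3.82 with equal numbers of peaks, 3.39 away from promoters and 11.5 among regions with a stronger peak. All of these lay above 1 by more than their counting intervals. Simulated detection that differed between whole lists, without an effect, gave only 1.14 in a single run. The ratio thus responded little to list length, so the run with equal numbers of peaks is a weak check. Of the 3648 regions, 3475 were away from promoters, so leaving promoters out could change the ratio little. The simulation held no detection difference that varied along the genome, so 1.14 is not a bound. Random calling of weak peaks would itself move the ratio towards 1, so the value among stronger peaks cannot decide on that explanation. Within deciles of local gene density the odds ratio was 3.09 and within chromosomes 3.21. These values argue against a gene-density trend and against copy number of whole chromosomes as the sole cause. Loss of ARID1A is a candidate explanation, and it cannot be separated from any other stable difference between the shControl and shARID1A cells or their libraries, because each genotype was represented by 1 library per treatment.

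Chromosomes with few genes had lower ratios of distal peaks with knockdown: over 23 chromosomes, which are not independent samples, Spearman's rho between protein-coding genes per Mb and the distal log2 ratio was 0.723 in DMSO and 0.722 under rapamycin, and Pearson's r 0.641 and 0.642. Without chromosomes 19 and 17, the farthest from the median density, r was 0.684 and 0.497. The ratios ranged from -0.51 on chromosome 13 to -0.02 on chromosome 22 in DMSO, and from -0.36 on chromosome X to -0.04 on chromosome 19 under rapamycin. Libraries of the same genotype also differed along gene density, with rho 0.480 for rapamycin against DMSO in shControl (r 0.287, and 0.638 without those chromosomes) and -0.604 in shARID1A (r -0.512, and -0.511). The trend may therefore underlie part of the loss of distal peaks without being specific to knockdown. Between libraries of the same genotype the ratios spanned less, from -0.19 to -0.02 in shControl and from -0.12 to 0.07 in shARID1A. Differences in library quality, rapamycin and ARID1A all stay open as its source. So do the numbers skipped in shARID1A DMSO, except for the knockdown trend under rapamycin, which does not use that list.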

How the results depend on the processing

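Filling in skipped numbers, and the restrictions of the odds ratio to stronger peaks and to regions outside skip intervals, were alternatives chosen after seeing the data. With the same number of top-ranked peaks from every list, 9053 peaks were lost with knockdown in DMSO and 7386 with rapamycin in shControl, 156 genes lost a promoter peak with knockdown in DMSO, and the knockdown odds ratio was 3.82. Under rapamycin 270 genes then lost a promoter peak with knockdown and 419 gained one, which turned the balance of 373 and 324. The counts of lost peaks fell because weak peaks of the longer list were removed. Among the stronger 50% of each list, lost and gained peaks were 1150 and 468 with knockdown in DMSO, 1051 and 530 under rapamycin, and 667 and 429 in shControl and 463 and 300 in shARID1A with rapamycin. With skipped numbers filled in, 5608 peaks were gained with rapamycin in shARID1A. Filling in only removed changed peaks and added none in the other direction. Among the stronger 50%, filling in would leave 587 of the 1150 peaks lost with knockdown in DMSO. It would leave 166 of the 300 stronger peaks gained with rapamycin in shARID1A. With a reciprocal overlap of 50%, 12692 peaks were gained with knockdown under rapamycin. At promoters the knockdown and rapamycin odds ratios were 1.86 and 0.722, and among regions with a stronger peak 11.5 and 1.29. Outside intervals with skipped numbers they were 3.01 and 0.997. Apart from the effect of list length named above, the cause was not tested. Counts of lost peaks lay within 1.5 times the reported count in 14 of 20 alternatives, of gained peaks in 14 of 20, of genes losing a promoter peak in 11 of 12 and of genes gaining one in 12 of 12. Of 112 list values under other windows or peak numbers, 10 crossed the bounds of the central 95% of random lists and 102 did not. Motif shares were not run, since no genome sequence was used. Unknown read depth limits every count of absent peaks, and with 1 library per group none has a replicate check.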

Other observations

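The summary of regions shared by both lists of a genotype around genes, and the stretch of chromosome 11, were chosen after the values were seen.

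Some genes had several regions open only in both shControl lists within 50 kb of their TSS. At least 3 such regions and none of the opposite kind surrounded 19 genes. Among them were LIPC, encoding hepatic lipase, SMAD3, a signal transducer of the TGF-beta pathway, MAOA, encoding a monoamine oxidase, the histone demethylase family gene JMJD1C, the lysophosphatidic acid receptor gene LPAR3, the guanine exchange factor gene TRIO and LITAF. LIPC had 10 and 10 peaks within 50 kb in shControl DMSO and rapamycin and 7 and 7 in shARID1A, TRIO 13 and 14 and 10 and 7, and LITAF 7 and 8 and 4 and 4. The opposite kind surrounded 3 genes, KCNH2, a potassium channel gene, NOS3, encoding endothelial nitric oxide synthase, and the autophagy gene ATG9B. These are neighbours on chromosome 7 between 150944961 and 151024499 and share regions. Neighbours among the 19 genes, NOP16 and HIGD2A on chromosome 5 and JMJD1C and REEP3 on chromosome 10, can share regions too. Over the genome, 3648 regions were open only in both shControl lists and 1265 only in both shARID1A lists. Outside intervals with skipped numbers these were 1933 and 1087. KCNH2 had 5 and 5 peaks in shControl and 8 and 8 in shARID1A, and ATG9B 6 and 6 and 9 and 10.

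Between 57 and 69 Mb on chromosome 11 lay 37, 41, 40 and 41 of the 100 top-ranked peaks in shControl DMSO, shControl rapamycin, shARID1A DMSO and shARID1A rapamycin. Distal regions in the decile with the fewest genes nearby were lost with knockdown in 44.9% in DMSO and 38.0% under rapamycin, against 26.7% and 28.4% in the decile with the most. With rapamycin the same shares were 29.7% and 25.7% in shControl and 24.3% and 27.6% in shARID1A.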
